A study of Mus musculus with 12 samples.

How the data were processed

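NIH-3T3 cells, an established mouse fibroblast line, were grown with no 4-thiouridine (4sU), 200 µM 4sU or 800 µM 4sU for 2 h, per the labels' protocols. 4sU is a uridine analogue that cells build into RNA made during labelling. In SLAM-seq, iodoacetamide alkylates the 4sU so that reverse transcription reads it as C. The conversion was done either on isolated RNA in tubes or inside methanol-fixed cells, and per the labels' protocols the procedures also differed in reaction temperature and time. Each of the 6 groups held 2 libraries, replicates A and B, and the labels name no batch.

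One deposited table of 15217 genes was used. Its read counts are expected counts per gene and library, per the file headers and the values, since 16.2% to 22.0% of the values in a library were not whole numbers. How the authors divided reads between genes is not given in the sources used here. The counts were rounded to whole numbers before testing. For the 8 libraries with 4sU, the deposited table also gives the new-to-total ratio of each gene, a fraction between 0 and 1, as its maximum a posteriori value, its posterior mean and the 0.05 and 0.95 quantiles, per the file headers. The deposited alpha and beta values are scores, the parameters of the beta distribution behind that fraction, and were used only to check the columns. The submitters' processing notes name cutadapt, Bowtie2 2.3.0 and STAR 2.7.10b, without their roles. The genome build, the annotation and the tool that estimated the ratio are not given in the sources used here. The deposited table gives no ratio for the libraries without 4sU, so the ratio has no background from unlabelled cells. Gene IDs were matched to GENCODE M21 (GRCm38), where 15185 were found and 32 were not. All coordinates are those of GENCODE M21 on GRCm38, by gene ID, and length is the deposited value.

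Library totals ranged from 3629634 to 7762635 counts. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 11080 genes holding at least 99.92% of the counts of a library. Differences in counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM scaling and Benjamini-Hochberg (BH) adjustment at 0.05, in 1 fit of the 6 groups and 12 libraries without a replicate block. The residual degrees of freedom were 6, the median prior degrees of freedom 12.1 and the common biological coefficient of variation 12.3%. The 9 comparisons were 4sU against no 4sU at each dose in each procedure, the difference between the procedures in that effect at each dose, fixed cells against tubes without 4sU, and the dose step in each procedure.

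Before the data were examined, 21 gene lists were fixed. Of these, 19 had enough tested members: immediate early genes, p53 targets, integrated stress response, heat shock, endoplasmic reticulum stress, interferon response, NF-kappaB targets, glycolysis, cytosolic ribosomal proteins, extracellular matrix and secreted proteins, cholesterol synthesis, nuclear long noncoding RNAs, small nucleolar RNA host genes, mitosis, S phase, replication-dependent histones, zinc finger genes with a Zfp symbol, actin cytoskeleton with serum response factor targets, and markers of other cell types. Mitochondrially encoded genes and small noncoding RNAs had 0 members in the table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation, with BH adjustment over the lists of a comparison.

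The genes named in the text were chosen by a rule fixed before the data were examined. For the 800 µM comparisons (each procedure and their difference) and for fixed cells against tubes, these were the 6 largest rises and the 6 largest falls among genes past the threshold, with a mean count of at least 50 and the same direction in both replicates, and the 3 members with the smallest p of each list that camera called. For the comparisons at 200 µM and for the dose steps the rule took 3 rises and 3 falls. For the ratio it took the 6 genes with the highest and the 6 with the lowest mean. Gene models without a common symbol, such as Gm and Rik names, were passed over. Where no gene passed, the 3 with the smallest p were named. Gapdh, Actb, Malat1, Myc and Fos were named in every comparison. Some genes that the rule takes are not reported here.

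The bias against labelled RNA was measured in each 4sU library across genes with a mean count of at least 100 in the libraries without 4sU of the same procedure. Spearman's correlation between the ratio and the log2 fold against those libraries was computed, and the estimated loss of labelled RNA is the share that had to be added back for this correlation to be 0. Procedures were compared by an exact permutation of libraries within doses, two-sided, with 36 arrangements and a smallest possible p of 0.056. Ratios of single genes were compared with limma (trend) on the logit scale, at genes with a count of at least 100 in each of the 8 libraries, with ratios limited to 0.01 and 0.99.

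The edgeR test, the loss estimate and the ratio test were tried on simulated data. With counts simulated for the 11080 genes, the edgeR test of 800 µM in tubes recovered 80.6% of genes changed 2-fold and 17.9% of those changed 1.5-fold. For the difference between procedures at 800 µM it recovered 34.3% at 2-fold and 95.5% at 4-fold. Simulated losses of 20% and 40% over the 6245 genes of the tube procedure were estimated as 20.3% and 40.3%. Those libraries were drawn with Poisson noise alone from the mean of their own controls, with ratios known without error. The simulated losses therefore check the computation and not the spread between libraries. Over 5532 genes, the ratio test at 800 µM recovered 5.97% of genes with a logit shift of 0.5, 43.3% at 1 and 90.9% at 2. Few of the 5532 genes were shifted there, all upward, and the rest were not shifted. Other settings tried were DESeq2 size factors, TMM on the third of genes with the lowest ratio, no filter, DESeq2 1.42.0 in place of edgeR, a replicate block, a fit of the compared groups alone, a minimum fold of 1.2, other count minimums, other controls for the loss, and leaving out each library in turn. Plots were drawn with matplotlib 3.10.9.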

Results

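Total RNA levels and the share of newly made RNA were measured by SLAM-seq in NIH-3T3 cells, an established line of mouse embryonic fibroblasts. The cells received no 4sU, 200 µM 4sU or 800 µM 4sU for 2 h, and the 4sU was converted in tubes on isolated RNA or inside methanol-fixed cells. Each of the 6 groups held 2 libraries, A and B. In the tube procedure, library totals were 3629634 and 4585474 counts without 4sU, 4542666 and 5676517 at 200 µM, and 7504638 and 6654809 at 800 µM. In fixed cells they were 5385243 and 6211608 without 4sU, 7762635 and 7510540 at 200 µM, and 5840808 and 6359853 at 800 µM. Of 15217 genes, 11080 passed the filter on low counts. Log counts of libraries within a group correlated at 0.976 to 0.986 across genes, and no pair of replicates had counts within sampling noise of each other (chi-square per degree of freedom 3.23 to 22.8). The first principal component held 47.4% of the variance. On it, fixed 800 µM library A lay at 45.4 and library B at 27.9, and the TMM factors of these libraries were 0.835 and 0.94. Nothing in the labels says that A and B were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

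The first comparisons asked how 4sU treatment moved total RNA levels when conversion took place in tubes. At 800 µM, Nr4a1, an immediate early gene for an orphan nuclear receptor, rose by a log2 change of 1.93 (SE 0.19, n = 2 libraries per group, edgeR quasi-likelihood test with BH-adjusted p = 6.02e-05). Its level went from 33.2 ± 11.3 CPM (counts scaled to the effective library size; SD, n = 2) without 4sU to 124.9 ± 14.3 CPM. The epidermal growth factor receptor ligands Ereg and Hbegf rose by 1.77 (SE 0.24) and 1.46 (SE 0.15), and Cdkn1a, the p53-induced cell cycle inhibitor p21, by 1.42 (SE 0.16; edgeR BH-adjusted p = 9.7e-05). Ereg went from 14.8 ± 5.56 to 50.1 ± 1.85 CPM and Cdkn1a from 101.9 ± 21 to 271.4 ± 20.8 CPM (SD, n = 2). Spred2, an inhibitor of Ras signalling to MAP kinases, rose by 1.41 (SE 0.29), and Egr3, an immediate early transcription factor, by 1.33 (SE 0.22). Fam208a, a component of the HUSH silencing complex, fell with a log2 change of −1.49 (SE 0.32), and Mettl14, a subunit of the N6-methyladenosine methyltransferase, with −1.36 (SE 0.26). Falls were also found for Nemp1, a nuclear envelope protein, with −1.31 (SE 0.29), Zmym2, a zinc finger protein, with −1.23 (SE 0.18), Pias1, a SUMO ligase, with −1.20 (SE 0.22), and Mertk, a receptor tyrosine kinase, with −1.12 (SE 0.26). In all, 101 genes rose and 106 fell, of which 67 changed over 2-fold, and each gene named by rank moved the same way in both replicates. With each library of the compared groups left out in turn, 6 of the 23 named genes past the threshold passed every time, among them Cdkn1a, Ereg, Hbegf, Nr4a1 and Zmym2. Gapdh lay at 0.11 (SE 0.23; −0.010 with scaling on the third of genes with the lowest ratio), Actb at 0.18 (SE 0.14), Fos at 0.73 (SE 0.66), Myc at 0.29 (SE 0.34) and Malat1 at −0.19 (SE 0.19), and none of these 5 passed.

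Of 21 p53 targets tested at 800 µM in tubes, 4 rose and 0 fell over all genes (7 and 1 adjusted over the list alone). Among them were Cdkn1a, Mdm2, the ubiquitin ligase of p53, at 1.03 (SE 0.20), and Ccng1, a cyclin induced by p53, at 0.69 (SE 0.14). For the p53 targets, camera gave a BH-adjusted p = 0.000292, and an adjusted p = 0.0363 with an estimated correlation. Of 278 zinc finger genes, 0 rose and 2 fell (the same counts adjusted over the list alone), namely Zfp367 at −1.01 (SE 0.18) and Zfp639 at −0.89 (SE 0.17), with a list median of −0.08. Across all genes the log2 fold followed transcript length here with a Spearman's rho of −0.137, and its median was 0.15 in the tenth of genes with the shortest lengths and −0.06 in the tenth with the longest. For the zinc finger genes, camera gave a BH-adjusted p = 0.0112, and an adjusted p = 0.0273 with an estimated correlation. Of 29 genes of matrix and secreted proteins, 4 rose and 0 fell (4 and 0 adjusted over the list alone). They included the protease inhibitor Timp1 at 0.60 (SE 0.14) and the matrix protein Thbs1 at 0.85 (SE 0.15). For the matrix and secreted proteins, camera gave a BH-adjusted p = 0.00036, and an adjusted p = 0.22 with an estimated correlation. Of 35 immediate early genes, 4 rose and 2 fell (5 and 3 adjusted over the list alone). Nr4a1 and Egr3 were among the rises and Ier5 at −0.74 (SE 0.13) among the falls. For immediate early genes, camera gave a BH-adjusted p = 0.0292, and an adjusted p = 0.22 with an estimated correlation. Of 15 NF-kappaB targets, 3 rose and 0 fell (4 and 1 adjusted over the list alone). These were the cytokine Lif at 2.59 (SE 0.43, mean count under 50), the chemokine Ccl2 at 0.94 (SE 0.19) and Ptgs2, a prostaglandin synthase, at 0.77 (SE 0.16). The list's median was 0.08, or −0.04 with scaling on the third of genes with the lowest ratio. For the NF-kappaB targets, camera gave a BH-adjusted p = 0.0267, and an adjusted p = 0.235 with an estimated correlation.

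Other lists moved as sets in camera at 800 µM in tubes without members past the threshold over all genes. Over all 4sU libraries, median new-to-total ratios were low for the rising ribosomal protein (11.7%), glycolysis (14.8%), cytoskeletal (17.2%) and matrix lists (19.9%). They were 81.2% for the falling zinc finger list and 46.1% for mitosis. Loss of labelled RNA could move these lists in the same directions, which was not tested. The rising p53 (79.6%), immediate early (94%) and NF-kappaB lists (94.6%) moved against that direction. The 78 ribosomal protein genes had a median of 0.22 with 0 calls (0 adjusted over the list alone), beside the rho of −0.137 between log2 fold and length across all genes. For the ribosomal protein genes, camera gave a BH-adjusted p = 7.66e-06, and an adjusted p = 0.537 with an estimated correlation. Cytoskeletal genes and serum response factor targets had a median of 0.21 over 22 genes (3 rises adjusted over the list alone), with the tubulin Tubb6 at 0.80. For the cytoskeletal genes, camera gave a BH-adjusted p = 0.00374, and an adjusted p = 0.0644 with an estimated correlation. The 15 glycolysis genes had a median of 0.26 (0 calls adjusted over the list alone), with the lactate dehydrogenase Ldha at 0.36 (SE 0.13) but the hexokinase Hk2 at −0.44 (SE 0.14). For the glycolysis genes, camera gave a BH-adjusted p = 0.0292, and an adjusted p = 0.244 with an estimated correlation. The 10 interferon response genes had a median of −0.54 (1 fall adjusted over the list alone), with Irf1, a transcription factor of that response, at −0.94 (SE 0.26). Too few of these 10 had at least 100 counts and a ratio in each 4sU library to give a list ratio, so this median rests mostly on genes with lower counts. For the interferon response genes, camera gave a BH-adjusted p = 0.0185, and an adjusted p = 0.218 with an estimated correlation. The 20 mitosis genes had a median of −0.19 (0 calls adjusted over the list alone), with the mitotic kinase Aurka at −0.43. For the mitosis genes, camera gave a BH-adjusted p = 0.0292, and an adjusted p = 0.235 with an estimated correlation. Camera did not call the integrated stress response with 1 fall (BH-adjusted p = 0.401), heat shock with 0 calls (0.401), endoplasmic reticulum stress with 1 fall (0.459) and cholesterol synthesis with 0 (0.0529). Nor did it call nuclear long noncoding RNAs with 0 (0.785), small nucleolar RNA host genes with 0 (0.0574), S phase with 1 rise (0.269), histones with 0 (0.459) and markers of other cell types with 0 of 4 (0.612). Of the 10 called lists, 5 lost the call when 1 library was left out. Without tube 800 µM library A, the camera BH-adjusted p was 0.0547 for immediate early genes, 0.0811 for NF-kappaB targets and 0.131 for the interferon list. Without the tube library B that had no 4sU, it was 0.213 for immediate early genes, 0.0763 for NF-kappaB targets and 0.0525 for both glycolysis and mitosis. Without the tube library A that had no 4sU it was 0.0799 for glycolysis and for mitosis, and without tube 800 µM library B 0.112 and 0.169.

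At 200 µM in tubes, 262 genes rose and 154 fell (edgeR with BH adjustment), 86 of them over 2-fold. Nr4a1 rose by 1.85 (SE 0.19), Angptl4, a secreted inhibitor of lipoprotein lipase, by 1.58 (SE 0.14) and Slc30a1, a zinc exporter, by 1.53 (SE 0.19; edgeR BH-adjusted p = 0.000358). The homeobox gene Hoxc6 fell with a log2 change of −1.81 (SE 0.36), the kinesin gene Kif20b with −1.51 (SE 0.19) and Mtbp, whose product binds Mdm2, with −1.49 (SE 0.32). The nuclear long noncoding RNA Malat1 fell with −0.85 (SE 0.19; edgeR BH-adjusted p = 0.0248), from 2320 ± 68.4 to 1286 ± 503 CPM (SD, n = 2). Gapdh lay at 0.03 (SE 0.23; −0.088 with scaling on the third of genes with the lowest ratio), Actb at −0.02 (SE 0.14), Fos at 0.82 (SE 0.68) and Myc at −0.73 (SE 0.37), and none of these 4 passed. Of the 78 ribosomal protein genes, 10 rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 0.38, where log2 folds across all genes had a Spearman's rho with transcript length of −0.196 (median 0.19 in the tenth of genes with the shortest lengths and −0.12 in the tenth with the longest). For these ribosomal protein genes, camera gave a BH-adjusted p = 3.2e-13, and an adjusted p = 0.489 with an estimated correlation. Of 29 matrix and secreted protein genes, 4 rose and 0 fell (10 and 1 adjusted over the list alone). For these matrix genes, camera gave a BH-adjusted p = 4.87e-05, and an adjusted p = 0.23 with an estimated correlation. Of 278 zinc finger genes, 0 rose and 4 fell (0 and 1 adjusted over the list alone), with a camera BH-adjusted p = 0.0532 but an adjusted p = 0.0474 with an estimated correlation. Of the 7 named genes past the threshold, Angptl4, Kif20b, Nr4a1 and Slc30a1 passed with each library of the compared groups left out. The counts of called genes in tubes rested on single libraries. At 200 µM the count of 416 was 39 and 51 without library A or B that had no 4sU, and 210 and 17 without the 200 µM library A or B. At 800 µM the count of 207 was 91 and 27 without library A or B that had no 4sU, and 30 and 17 without the 800 µM library A or B. In these fits a group with 1 library left is assumed to vary like the others. With scaling on the third of genes with the lowest ratio, which moved the median of all genes by −0.12 at both doses, the splits were 100 higher and 281 lower at 200 µM and 56 and 217 at 800 µM.

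In fixed cells at 800 µM, Ereg rose by 1.70 (SE 0.25, n = 2 per group, edgeR BH-adjusted p = 0.00138), and the cytokine Il11 by 1.35 (SE 0.30). Egr3 rose by 1.32 (SE 0.24), Hbegf by 1.31 (SE 0.15) and Angptl4 by 1.28 (SE 0.14). Rgma, a co-receptor for bone morphogenetic proteins, fell with a log2 change of −1.70 (SE 0.22), and Irs1, the insulin receptor substrate, with −1.53 (SE 0.18; edgeR BH-adjusted p = 0.000258). Mettl14 fell with −1.45 (SE 0.27), Fam43a with −1.42 (SE 0.20), Sertad3 with −1.42 (SE 0.25) and the kinase gene Pim3 with −1.39 (SE 0.20). Irs1 went from 55.1 ± 3.08 to 19.0 ± 1.05 CPM (SD, n = 2). In all, 86 genes rose and 209 fell, of which 98 changed over 2-fold. Nr4a1, named for its rise in tubes, rose by 1.12 (SE 0.18; edgeR BH-adjusted p = 0.00301). With each library of these groups left out in turn, 8 of the 21 named genes past the threshold passed every time, among them Angptl4, Cdkn1a, Fam43a, Hbegf, Irs1, Pim3 and Rgma. Gapdh lay at 0.39 (SE 0.23), Actb at −0.18 (SE 0.14), Fos at −0.37, Myc at −0.12 and Malat1 at 0.19, and none of these 5 passed.

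Of the 21 p53 targets, 3 rose and 0 fell in fixed cells at 800 µM (4 and 0 adjusted over the list alone). Cdkn1a rose by 1.09 (SE 0.15), Mdm2 by 1.21 (SE 0.21) and the nuclease gene Aen by 0.87 (SE 0.18). The list's median was 0.05, or −0.09 with scaling on the third of genes with the lowest ratio. For these p53 targets, camera gave a BH-adjusted p = 0.0335, and an adjusted p = 0.18 with an estimated correlation. Camera's BH-adjusted p became 0.114 without library A that had no 4sU and 0.0623 without 800 µM library A. Of 20 mitosis genes, 2 fell and 0 rose (5 and 0 adjusted over the list alone). Cdc20, the activator of the anaphase-promoting complex, fell with −0.70 (SE 0.13) and the kinetochore motor gene Cenpe with −0.55 (SE 0.13). For these mitosis genes, camera gave a BH-adjusted p = 0.00338, and an adjusted p = 0.192 with an estimated correlation. That BH-adjusted p was 0.0945 without 800 µM library B. Of 78 ribosomal protein genes, 4 rose and 0 fell (40 and 0 adjusted over the list alone). Their median was 0.39, with Rpl21 at 0.87 (SE 0.22) and Rpl11 at 0.70 (SE 0.18), where log2 folds across all genes had a Spearman's rho with transcript length of −0.204 (median 0.22 in the tenth of genes with the shortest lengths and −0.10 in the tenth with the longest). For the ribosomal list, camera gave a BH-adjusted p = 1.07e-17, and an adjusted p = 0.364 with an estimated correlation. Without 800 µM library A, that median was 0.16 with 1 rise (camera BH-adjusted p = 0.000238, and adjusted p = 0.678 with an estimated correlation). Of 22 cytoskeletal genes, 1 rose, Tubb6, by 1.17 (SE 0.20; 8 rises adjusted over the list alone). For the cytoskeletal list, camera gave a BH-adjusted p = 0.00054, and an adjusted p = 0.0841 with an estimated correlation. The 15 glycolysis genes had 0 calls (1 rise adjusted over the list alone) and a median of 0.31, with Ldha at 0.48. For the glycolysis list, camera gave a BH-adjusted p = 0.00712, and an adjusted p = 0.262 with an estimated correlation. With a library left out, it was 0.0754 without 800 µM library A and 0.0706 without library B that had no 4sU. Camera did not call the immediate early genes, with 4 rises and 4 falls (BH-adjusted p = 0.594), or the NF-kappaB targets, with 2 rises (0.378). Nor did it call the matrix list, with 1 rise and a median of 0.08 (0.0818), but without 800 µM library A that median was 0.23 with 4 rises (camera BH-adjusted p = 5.54e-05, and adjusted p = 0.0689 with an estimated correlation).

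At 200 µM in fixed cells, 27 genes rose and 63 fell (edgeR with BH adjustment), 35 of them over 2-fold. Ereg rose by 1.52 (SE 0.25), the SUMO protease gene Senp3 by 1.49 (SE 0.34) and Egr3 by 1.29 (SE 0.23; edgeR BH-adjusted p = 0.0148). Pim3 fell with −1.48 (SE 0.19), Bard1, the partner of Brca1 in DNA repair, with −1.38 (SE 0.25) and Fam43a with −1.32 (SE 0.19). Gapdh lay at 0.15, Actb at 0.24, Fos at 0.78, Myc at 0.24 and Malat1 at 0.01 (−0.070 with scaling on the third of genes with the lowest ratio), and none of these 5 passed. Camera called mitosis genes, median −0.22, with 1 fall (5 adjusted over the list alone; BH-adjusted p = 0.000212, and adjusted p = 0.124 with an estimated correlation). It called matrix and secreted protein genes, median 0.15, with 2 rises (3 adjusted over the list alone; BH-adjusted p = 3.29e-05, and adjusted p = 0.174 with an estimated correlation). It also called cytoskeletal genes with 1 rise (1 adjusted over the list alone; BH-adjusted p = 0.00067, and adjusted p = 0.0548 with an estimated correlation). Interferon response genes, median −0.58, were called with 1 fall (2 adjusted over the list alone; BH-adjusted p = 0.00962, and adjusted p = 0.174 with an estimated correlation; 0.0919 without 200 µM library A). Few of these interferon genes had at least 100 counts and a ratio in each 4sU library. Ribosomal protein genes had a median of 0.17 with 0 calls (0 adjusted over the list alone), where the rho between log2 fold and length across all genes was −0.154 (median 0.12 in the tenth of genes with the shortest lengths and −0.07 in the tenth with the longest). For ribosomal protein genes here, camera gave a BH-adjusted p = 2.73e-06, and an adjusted p = 0.682 with an estimated correlation. Camera's BH-adjusted p became 0.0527 without 200 µM library B. None of the 6 named genes past the threshold at 200 µM passed with each library of the compared groups left out. The count of 90 genes at 200 µM was 9 and 1 without library A or B that had no 4sU, and 3 and 4 without the 200 µM library A or B. At 800 µM the count of 295 was 32 and 36 without library A or B that had no 4sU. It was 245 without 800 µM library A (117 higher and 128 lower, with 128 of the 295 kept) and 1211 without 800 µM library B (720 higher and 491 lower). Scaling on the third of genes with the lowest ratio gave 18 higher and 145 lower at 200 µM, and at 800 µM, where it moved the median of all genes by −0.14, 46 and 537. At 800 µM, where the main split was 86 and 209, DESeq2 size factors in edgeR gave 167 and 185, and DESeq2 in place of edgeR gave 331 and 226.

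**Figure D1:**
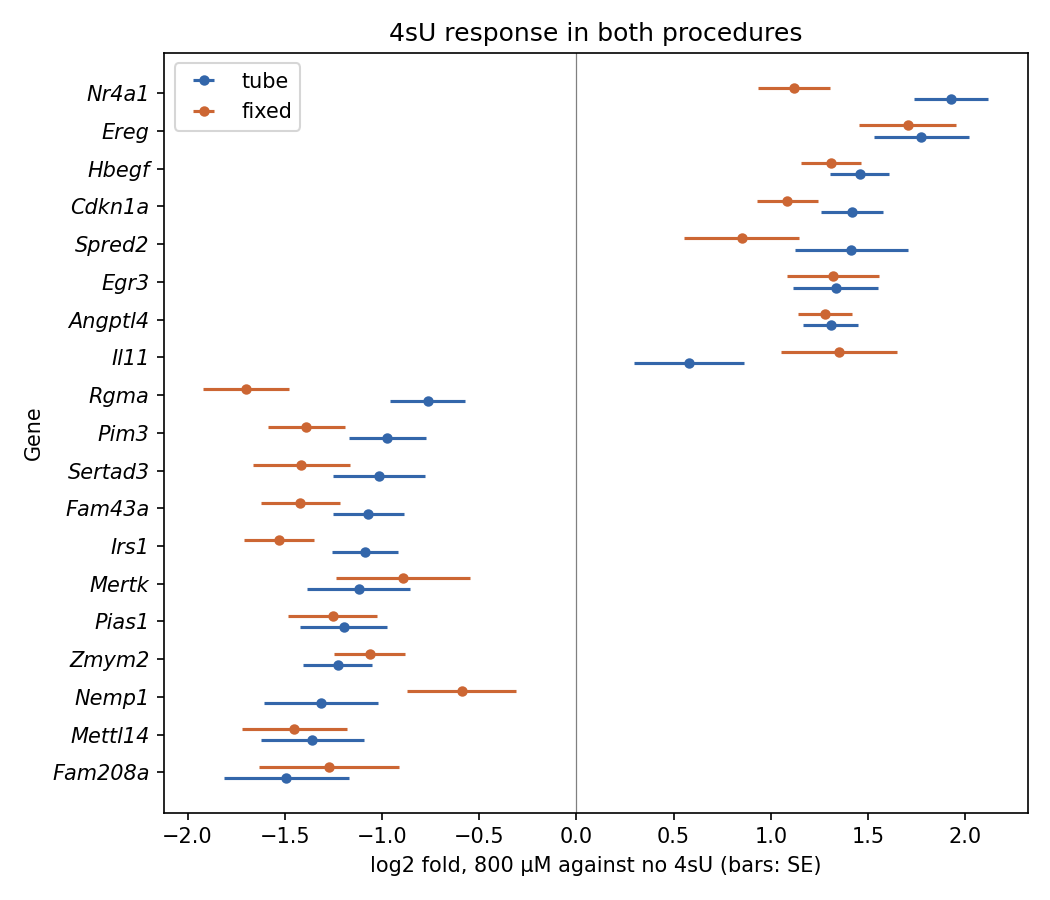
The plot shows the log2 fold change of 19 named genes at 800 µM 4sU against no 4sU on the horizontal axis, with bars of 1 SE from the edgeR fit, for tubes (blue) and fixed cells (orange), n = 2 libraries per group. Ereg lies at 1.77 in tubes and 1.70 in fixed cells, and Irs1 at −1.09 and −1.53.

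The next comparisons asked whether the procedure changed the response to 4sU. Tubes and fixed cells share no libraries, but their calls came from 1 fit with the same estimated spread per gene. Counts for independent lists take each gene as equally likely to be called, so they are no test of a shared response. The shared spread does not set the direction of a change. The lower levels of genes with a high new-to-total ratio, found in every 4sU library, could do so. At 800 µM, 33 genes rose in both procedures and 65 fell in both, where independent lists of these sizes would share 0.784 and 2, and 0 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 folds of the procedures correlated with a Pearson's r of 0.419 at 800 µM and 0.284 at 200 µM (Spearman's rho 0.436 and 0.307). At 200 µM, 16 genes rose and 19 fell in both, against 0.638 and 0.876 for independent lists. No single gene passed the test of the difference itself by edgeR with BH adjustment. It gave 0 calls at 200 µM (993 genes at an unadjusted p under 0.05, against 554 by chance, and 9 calls by DESeq2) and 0 at 800 µM (654 at an unadjusted p under 0.05, and 0 by DESeq2). The smallest p at 200 µM were those of the lactate transporter Slc16a1 with a fixed minus tube difference of 1.16 (SE 0.21), Nfkb2 with −1.07 (SE 0.21) and Kif20b with 1.34 (SE 0.26), each with an edgeR BH-adjusted p of 0.147. At 800 µM they were those of Triobp with −1.03 (SE 0.22), Cep152 with −1.47 (SE 0.31) and the metalloprotease gene Mmp19 with 1.77 (SE 0.39), each with an edgeR BH-adjusted p of 0.796. Of the genes named throughout, Gapdh differed by 0.12 and 0.28 at 200 and 800 µM, Actb by 0.26 and −0.36, Myc by 0.97 and −0.42, and Malat1 by 0.86 and 0.39. Fos differed by −1.10 at 800 µM and by −0.04 at 200 µM (0.014 with DESeq2 size factors and 0.0024 with scaling on the third of genes with the lowest ratio), and none of the 5 passed. In simulated counts this test recovered 34.3% of genes with a 2-fold difference at 800 µM and 47.8% at 200 µM. Without fixed 800 µM library B it called 125 genes at 800 µM, and without the tube library B that had no 4sU 3 genes at 200 µM.

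Ribosomal protein genes were called by camera in the test of the difference at both doses, with opposite signs and 0 single calls. Their median difference, fixed minus tube, was −0.20 at 200 µM (camera BH-adjusted p = 0.0284, and adjusted p = 0.852 with an estimated correlation). It was 0.18 at 800 µM (camera BH-adjusted p = 0.000106, and adjusted p = 0.732 with an estimated correlation). At 800 µM the members with the smallest p were Rpl4 at 0.89 (SE 0.39), Rpl21 at 0.78 (SE 0.32) and Rpl17 at 0.72 (SE 0.35). Across all genes, the difference had a Spearman's rho with transcript length of 0.0801 at 200 µM and −0.0733 at 800 µM. Ribosomal protein genes have many processed pseudogenes, and how reads were shared between copies is not given in the sources used here, so their values are uncertain. The call at 200 µM was lost with DESeq2 size factors (camera BH-adjusted p = 0.0587), and without tube library A that had no 4sU (0.493), tube 200 µM library A (0.234), fixed library A that had no 4sU (0.177) or fixed 200 µM library A (0.617). The call at 800 µM was lost without tube 800 µM library A (0.131), tube library B that had no 4sU (0.281) or fixed 800 µM library A (0.816, with a median of −0.03).

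The dose step from 200 to 800 µM gave 0 calls by edgeR with BH adjustment in tubes (987 genes at an unadjusted p under 0.05, and 12 calls by DESeq2) and 0 in fixed cells (872, and 0 by DESeq2). In tubes the smallest p were those of Cdc42ep3 at 1.43 (SE 0.24; edgeR BH-adjusted p = 0.108), Cdc40, a splicing factor, at 1.01 (SE 0.20) and Slc16a1 at 0.75 (SE 0.15), the last pair each with 0.175. In fixed cells they were those of Trmt11 at −1.15 (SE 0.24), Nufip1 at −0.94 (SE 0.20) and Fstl1, a secreted glycoprotein, at −0.78 (SE 0.17), each with an edgeR BH-adjusted p of 0.47. Gapdh lay at 0.08 in tubes and 0.24 in fixed cells, Actb at 0.21 and −0.41, Fos at −0.09 and −1.15, Myc at 1.02 and −0.37, and Malat1 at 0.66 and 0.18. Ribosomal protein genes had a median of −0.13 in tubes (camera BH-adjusted p = 0.00136, and adjusted p = 0.766 with an estimated correlation; 0.104 without 200 µM library A and 0.371 without 800 µM library A). In fixed cells it was 0.24 (camera BH-adjusted p = 3.78e-09, and adjusted p = 0.696 with an estimated correlation), and −0.04 without 800 µM library A (0.772). The rho of the dose step with transcript length across all genes was 0.0977 in tubes and −0.112 in fixed cells. Without 800 µM library B, 484 genes were called in fixed cells, and without 200 µM library B 2 in tubes.

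Fixed cells without 4sU were compared with tubes without 4sU to show how the groups differed with no label. The procedure and a batch of libraries cannot be told apart in this comparison. The long noncoding RNA Neat1, the scaffold of nuclear paraspeckles, was lower in fixed cells by a log2 change of −2.64 (SE 0.14, n = 2 per group, edgeR BH-adjusted p = 2.26e-09), at 235.4 ± 0.0209 against 1472 ± 179 CPM (SD, n = 2). Malat1, a long noncoding RNA of nuclear speckles, was lower by −2.03 (SE 0.20), at 567.5 ± 2.64 against 2320 ± 68.4 CPM. Neat1 (ENSMUSG00000092274) lies on chromosome 19 at 5824708 to 5845478 and Malat1 (ENSMUSG00000092341) at 5795690 to 5802672, and both are annotated as lincRNA in GENCODE M21 (GRCm38). Also lower were the apoptosis gene Bax at −2.55 (SE 0.20), Ltbp2, which binds latent transforming growth factor beta, at −2.08 (SE 0.25), and the transcription factor gene Zfhx3 at −1.98 (SE 0.23). So was Zbed6 at −1.80 (SE 0.30), which lies within an intron of another gene and is uncertain. Higher in fixed cells were Spcs1, a signal peptidase subunit, at 1.96 (SE 0.18), the keratin gene Krt10 at 1.93 (SE 0.39), and the mitochondrial dehydrogenase gene Etfdh at 1.86 (SE 0.29). Hspb11 lay at 1.81 (SE 0.22), Rpl7a at 1.80 (SE 0.14) and Wdr83os at 1.78 (SE 0.14), which overlaps a gene on the opposite strand and is uncertain. In all, 1796 genes were higher and 1684 lower, 928 of them over 2-fold. Gapdh was higher by 0.82 (SE 0.23; edgeR BH-adjusted p = 0.0113) and Actb lower by −0.73 (SE 0.14; edgeR BH-adjusted p = 0.00063), while Fos at −0.55 (SE 0.76) and Myc at −0.43 (SE 0.36) did not pass. With each of the 4 libraries left out, 30 of the 32 named genes past the threshold passed every time, all but Gapdh and Meg3.

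Of 78 ribosomal protein genes, 62 were higher in fixed cells and 0 lower (63 and 0 adjusted over the list alone). Their median was 0.87, with Rpl23a at 1.61 (SE 0.13). For the ribosomal protein genes, camera gave a BH-adjusted p = 2.17e-31, and an adjusted p = 0.268 with an estimated correlation. Of 6 nuclear long noncoding RNAs, 3 were lower and 0 higher (the same counts adjusted over the list alone), Neat1, Malat1 and Meg3, the last at −0.66 (SE 0.19). For these long noncoding RNAs, camera gave a BH-adjusted p = 1.81e-05, and an adjusted p = 0.116 with an estimated correlation. Of 20 mitosis genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone). Among them were the mitotic kinases Cdk1 at 1.51 (SE 0.16), Bub1b at 1.34 (SE 0.18) and Plk1 at 0.98 (SE 0.15). For the mitosis list, camera gave a BH-adjusted p = 1.81e-05, and an adjusted p = 0.116 with an estimated correlation. Of 18 S phase genes, 9 were higher and 2 lower (the same adjusted over the list alone). The helicase subunit Mcm6 lay at 0.68 (SE 0.13) and the ribonucleotide reductase subunit Rrm2 at 0.67 (SE 0.13). For the S phase genes, camera gave a BH-adjusted p = 0.0297, and an adjusted p = 0.34 with an estimated correlation. That BH-adjusted p was 0.0556 without tube library B and 0.0528 without fixed library B. Of 22 histone genes, 9 were higher and 1 lower (the same adjusted over the list alone), with Hist1h2ag at 1.46 (SE 0.28), and near-identical copies make these values uncertain. For the histone genes, camera gave a BH-adjusted p = 0.0177, and an adjusted p = 0.447 with an estimated correlation. With a library left out, it was 0.0711 without tube library A. Of 29 matrix and secreted protein genes, 2 were higher and 12 lower (2 and 13 adjusted over the list alone). Fbln2, an elastic fibre protein, lay at −1.09 (SE 0.12), the basement membrane collagen Col4a2 at −1.07 (SE 0.17) and tenascin Tnc at −0.84 (SE 0.13). For the matrix list, camera gave a BH-adjusted p = 0.00155, and an adjusted p = 0.32 with an estimated correlation. Of 22 cytoskeletal genes, 10 were higher and 3 lower (the same adjusted over the list alone), with Tubb6 at 1.59 (SE 0.21) and smooth muscle actin Acta2 at 1.39 (SE 0.14). Their median was 0.20, or −0.04 with scaling on the third of genes with the lowest ratio. For the cytoskeletal list, camera gave a BH-adjusted p = 0.0297, and an adjusted p = 0.139 with an estimated correlation. Camera's BH-adjusted p became 0.0643 without tube library B. Camera did not call zinc finger genes, with 7 higher and 35 lower (1 and 22 adjusted over the list alone; BH-adjusted p = 0.195), immediate early genes, with 4 and 7 (0.208), or heat shock genes, with 5 and 2 (0.195). It did not call p53 targets, with 5 and 4, where a median of 0.25 stood against a test direction of lower (0.815).

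Across genes, the difference between fixed cells and tubes without 4sU followed transcript length, with a Spearman's rho of −0.416. The median log2 difference was 0.52 in the tenth of genes with the shortest deposited lengths (up to 1374) and −0.51 in the tenth with the longest (from 6755), 1108 genes each. Scaling on the third of genes with the lowest ratio moved the median of all genes by −0.24 and gave 1009 higher and 3008 lower. The count of 3480 was 2282 without tube library B, 2297 without fixed library A and 2134 without fixed library B.

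The new-to-total ratio is the deposited estimate of the share of a gene's RNA made during labelling. Transcripts of immediate early genes were estimated as mostly new after 2 h, with a list median of 94% over 25 genes (means over the 8 libraries), and NF-kappaB targets reached 94.6% over 7 genes. The list medians were 81.2% for zinc finger genes over 43 genes and 79.6% for p53 targets over 10. Within each of the 4 groups, though, the p53 targets lay higher, as with 82.3% against 79.5% in tubes at 200 µM. Nuclear long noncoding RNAs followed with 71.6% over 6. Mitosis genes had 46.1% over 16 genes, S phase genes 36.7% over 17 and matrix genes 19.9% over 25. Such values differed between groups, as for S phase genes from 44.6% in tubes at 200 µM to 28.4% in fixed cells at 800 µM. The lowest lists were cytoskeletal genes with 17.2% over 19, glycolysis genes with 14.8% over 12 and ribosomal protein genes with 11.7% over 78. Genes with the highest mean ratio over the 8 libraries, in an order that these narrow steps do not settle, were Clk1, a kinase of splicing factors, with 100%, Ajuba with 99.7%, Nr4a1 with 99.6%, the matricellular gene Cyr61 with 99.5%, Zfp770 with 99.3% and Irf2bp2 with 99.2%. The lowest were those of the growth factor Igf2 with 2.38%, Acta2 with 4.05%, the surface antigen Ly6a with 4.51%, Gchfr with 4.74%, the matrix protein Efemp1 with 4.94% and Pros1, which encodes protein S, with 4.97%. Their order also changed with the group. Gchfr lay at 2.86% and 1.85% in tubes at 200 and 800 µM and at 7.38% and 6.9% in fixed cells, with single libraries from 0% to 9.77%, and Igf2 at 4.41% and 2.54% in tubes and 2.58% and 0% in fixed cells. Ratios of the libraries ranked genes alike, with Spearman's rho across genes of 0.897 to 0.968 between libraries.

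The series concerns bias in quantification that depends on the procedure, so the ratio was compared between tubes and fixed cells. The median gene's ratio was 41.1% ± 1.74 in tubes and 35.3% ± 0.59 in fixed cells at 200 µM, and 36.3% ± 0.138 and 29% ± 4.33 at 800 µM (SD, n = 2). Over both doses the fixed minus tube difference in this median was −6.55 percentage points, and in it each fixed library lay below each tube library of its dose. An exact permutation within doses, two-sided, gave p = 0.0556, the smallest that 36 arrangements allow (BH-adjusted p = 0.278 over 5 measures). Genes with high ratios did not all follow this median. At 200 µM the zinc finger list had 79.5% in tubes but 84.6% in fixed cells, and the p53 targets 82.3% and 86.2%. At 800 µM these were 79.4% and 70.2%, and 80.3% and 72.6%. Ribosomal protein genes were lower in fixed cells at both doses, with 14% and 10.3% at 200 µM and 12.9% and 9.63% at 800 µM. Fixed 800 µM library A had a median of 26% and library B of 32.1%. In single genes, limma with BH adjustment gave 0 calls of 5532 genes at both doses, with 1030 genes at an unadjusted p under 0.05 at 200 µM and 1144 at 800 µM. The median difference on the logit scale was −0.19 at 200 µM and −0.31 at 800 µM. In simulated data at 800 µM this test recovered 5.97% of genes shifted by 0.5. Few genes were shifted there, all upward and with independent noise, so this value does not give the power for a shift of most genes. At 1615 genes with at least 500 counts in each library, limma with BH adjustment called 4 genes higher and 99 lower in fixed cells at 200 µM, and 2 and 203 at 800 µM. The counts of 0 rested on single libraries, also on those of the other dose, which share in the estimate of the spread. Without fixed 800 µM library B, 970 genes were called at 800 µM and 73 at 200 µM (33 higher and 40 lower in fixed cells). At 200 µM, 68 genes were called without fixed 800 µM library A (30 higher and 38 lower), and 1 without fixed 200 µM library A or without library B.

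**Figure D2:**
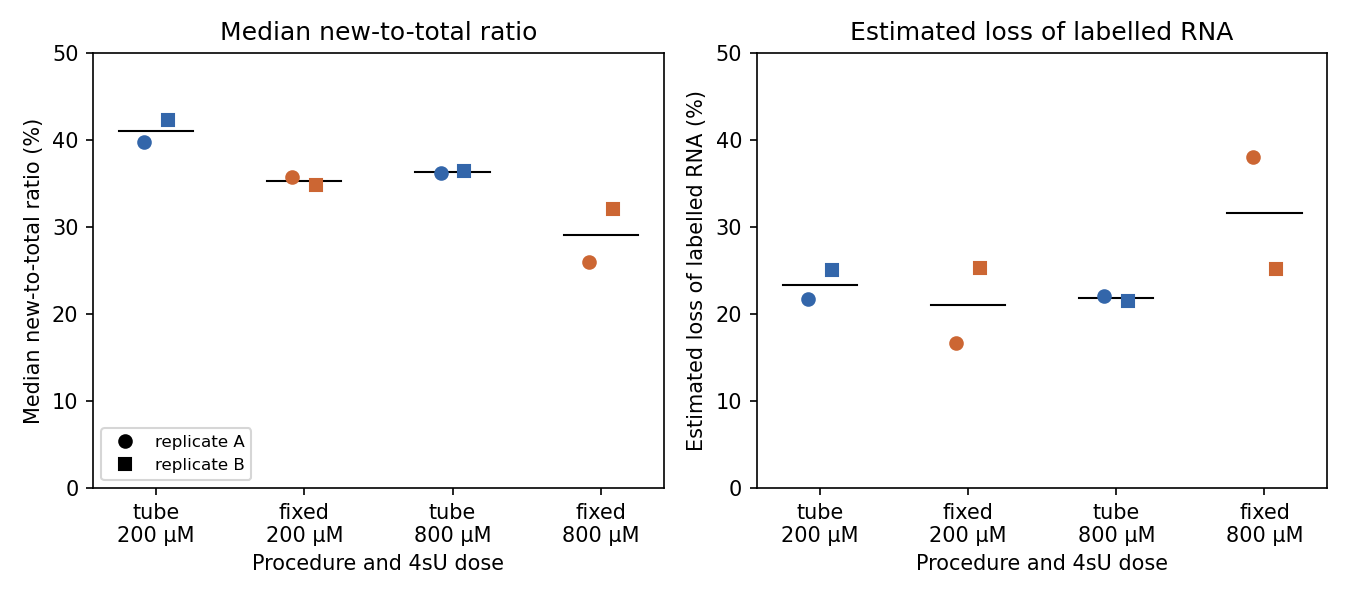
The panels show the median new-to-total ratio (%) and the estimated loss of labelled RNA (%) of each 4sU library by procedure and dose, with circles for library A, squares for library B and bars for the mean of 2. Ratios lie between 26% and 42.3% and losses between 16.7% and 38.1%, and fixed 800 µM library A has both the lowest ratio and the highest loss.

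In every 4sU library, genes with a larger share of new RNA had lower total levels relative to the libraries without 4sU. Spearman's rho across genes between the ratio and the log2 fold ran from −0.404 to −0.262 over the 8 libraries, where genes are not independent replicates. In tube 800 µM library B, the tenth of genes with the highest ratio had a median log2 fold of −0.11 and the tenth with the lowest 0.12 relative to all genes, and in fixed 800 µM library A the values were −0.28 and 0.23. The share of labelled RNA that had to be added back to bring the correlation to 0 was 23.4% ± 2.39 in tubes and 21% ± 6.05 in fixed cells at 200 µM (SD, n = 2). It was 21.8% ± 0.43 and 31.6% ± 9.14 at 800 µM (SD, n = 2). These values rest on 6245 genes in tubes and 6809 in fixed cells. Measured the same way between the libraries without 4sU, library B against A gave 2.84% in tubes and −0.537% in fixed cells. Over both doses the mean loss was 22.6% in tubes and 26.3% in fixed cells, a difference of 3.68 percentage points within the spread between libraries. An exact permutation within doses, two-sided, gave p = 0.556 (smallest possible 0.056, BH-adjusted p = 0.611 over 5 measures). The difference was −2.46 at 200 µM (exact permutation, two-sided, p = 1) and 9.82 at 800 µM (p = 0.33, the smallest possible). Without fixed 800 µM library A the joint difference was 0.448, without fixed 800 µM library B 6.91, without fixed 200 µM library A 5.82 and without fixed 200 µM library B 1.54. With the controls A alone it was 2.21 and with the controls B alone 5.53. The difference was also larger than 3.68 with the ratio of the other procedure at the same dose. Losses then ran from 18.8% to 23.7% in tubes and from 18.9% to 37.3% in fixed cells. At genes with a mean count of at least 500 the sign turned, with a loss difference of −3.49 and a difference in Spearman's rho of 0.0556. The fixed minus tube difference was −0.0637 in Spearman's rho (exact permutation, two-sided, p = 0.167, BH-adjusted 0.278) and −0.0802 in Pearson's r (p = 0.111, BH-adjusted 0.278). In the log2 gap between the tenth with the highest ratio and the tenth with the lowest it was −0.0572 (exact permutation, p = 0.611, BH-adjusted 0.611). The difference in rho also hung on single libraries, with rho of −0.262 and −0.404 in fixed 200 µM libraries A and B. Given transcript length and uracil content (partial Spearman's rho), each fixed library lay farther from 0 than each tube library of its dose. That difference was not tested. The libraries of a procedure share the same 2 controls, so these tests leave out the noise of the controls.

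**Figure D3:**
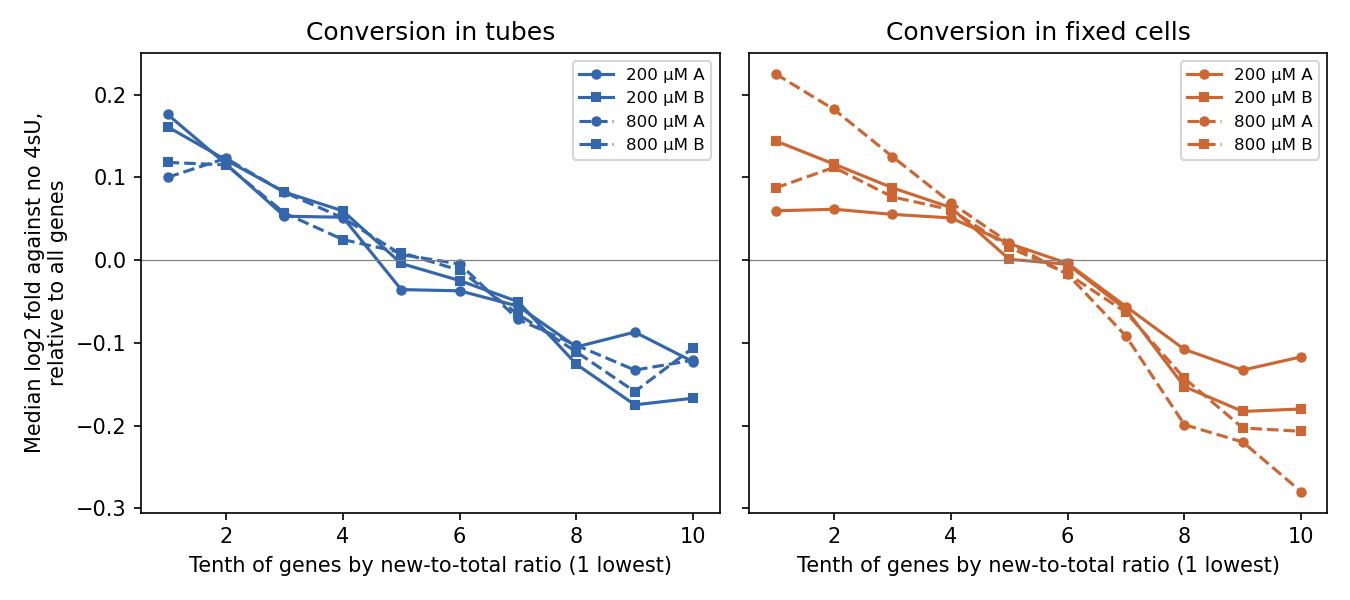
The panels show, for tubes and fixed cells, the median log2 fold against no 4sU relative to all genes, in 10 groups of genes ordered by their new-to-total ratio from lowest to highest, with a line per library (solid for 200 µM, dashed for 800 µM). Each line runs from a positive value at its left end to a negative one at its right end, with the widest span in fixed 800 µM library A from 0.23 to −0.28.

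Positions of the genes named most often are those of GENCODE M21 (GRCm38). Nr4a1 (ENSMUSG00000023034) lies on chromosome 15 at 101254269 to 101274795, and Ereg (ENSMUSG00000029377) on chromosome 5 at 91074622 to 91093646. Cdkn1a (ENSMUSG00000023067) lies on chromosome 17 at 29090976 to 29100727, Angptl4 (ENSMUSG00000002289) on chromosome 17 at 33773750 to 33781830 and Rpl7a (ENSMUSG00000062647) on chromosome 2 at 26910764 to 26913318.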

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

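Among the tests reported in this part, that of a greater loss of labelled RNA was chosen only after the result was seen, and its criterion was settled with the values known. The tests of the ribosomal protein list with a library left out were all chosen after seeing the data.

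Camera at its preset correlation called the ribosomal protein genes in the test of the difference between tubes and fixed cells in the response to 4sU, in opposite directions at the 2 doses, but neither call held with an estimated correlation (adjusted p = 0.852 at 200 µM and 0.732 at 800 µM). The median difference, fixed minus tube, was −0.197 at 200 µM and 0.181 at 800 µM, over 78 genes. By library, the list's median log2 fold over the libraries without 4sU was 0.394 and 0.383 in tubes at 200 µM, 0.12 and 0.314 in tubes at 800 µM, 0.087 and 0.271 in fixed cells at 200 µM, and 0.644 and 0.11 in fixed cells at 800 µM, for A and B in turn. At 800 µM the sign rested on fixed library A, since without it the median was −0.029 (camera BH-adjusted p = 0.816). The call at 800 µM was also lost without tube 800 µM library A (camera BH-adjusted p = 0.131) or the tube library B that had no 4sU (0.281), and that at 200 µM without tube library A that had no 4sU (0.493), tube 200 µM library A (0.234), fixed library A that had no 4sU (0.177) or fixed 200 µM library A (0.617).

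Fixed 800 µM library A also had lower new-to-total ratios than library B, with a median of 26% against 32.1%. Low counts per gene are argued against as the source, since at the 1615 genes with at least 500 counts in each library the ratio of A was still 0.812 times that of B. A mixture with RNA of unlabelled cells stayed open, because at the 207 genes called in tubes at 800 µM the response of A was 0.939 times that of B, with a bootstrap interval over genes of 0.878 to 1.004. A greater loss of labelled RNA in A as the whole cause stayed open too, though the median logit difference of −0.34 lay outside the −0.25 to −0.142 predicted from the losses (−0.189 at the centre), because that distance of −0.151 stood beside −0.141, 0.0064 and −0.0868 between the replicates of the other groups. The labels give no group that parts A from B, so no biological explanation was tested.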

How the results depend on the processing

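Of the settings in this part, the list tests and the median ratio with a library left out, and the ratio test without a library of the other dose, were chosen after seeing the data, and the rest were set before. Where a value below moved, the cause was not tested. Fits without a library have fewer samples, and an unfiltered test has more genes. The added genes are not the only change without the filter. Of 167 values of named genes, which the filter had kept, 28 newly passed without it and 0 no longer passed. Of 1902 values of named genes under other settings, 1633 kept their direction and their side of the threshold, 156 no longer passed, 77 newly passed and 36 changed sign. No named gene past the threshold changed sign when a library of the compared groups was left out. Every group holds 2 libraries, so the spread rests on few degrees of freedom, and the lowest total of 3629634 counts, in the tube library A without 4sU, limits low genes.

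Without the filter on low counts, edgeR called 854 genes in tubes at 200 µM, 482 in tubes at 800 µM, 252 in fixed cells at 200 µM, 816 in fixed cells at 800 µM, and 76 and 24 for the difference between procedures at 200 and 800 µM. For the dose step it called 92 in tubes and 127 in fixed cells. With a minimum fold of 1.2 the counts for 4sU against none were 48, 57, 11 and 96, in the same order. Fits of the compared groups alone turned the split in tubes at 200 µM round to 178 higher and 214 lower, and gave 391 in tubes at 800 µM, 676 and 43 in fixed cells at 200 and 800 µM, 13 for the difference at 200 µM and 17 for the dose step in tubes. Scaling on the third of genes with the lowest ratio gave 163 and 583 in fixed cells at 200 and 800 µM. DESeq2 in place of edgeR gave 557 in fixed cells at 800 µM, where the split turned round to 331 higher and 226 lower, 9 for the difference at 200 µM and 12 for the dose step in tubes.

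With 1 library of the compared groups left out, counts ranged from 17 to 210 in tubes at 200 µM, 17 to 91 in tubes at 800 µM, 1 to 9 in fixed cells at 200 µM, and 32 to 1211 in fixed cells at 800 µM. They ranged from 0 to 3 and 0 to 125 for the difference at 200 and 800 µM, 2134 to 2662 for fixed cells against tubes without 4sU, and 0 to 2 and 0 to 484 for the dose step in tubes and fixed cells. The lone library left in a group is assumed to vary like the other groups. The count of 1211 came without fixed 800 µM library B, as did 125 and 484. Of named genes past the threshold, all settings without a library of the compared groups kept 4 of 7 in tubes at 200 µM, 6 of 23 in tubes at 800 µM, 0 of 6 in fixed cells at 200 µM, 8 of 21 in fixed cells at 800 µM and 30 of 32 for fixed cells against tubes.

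Named genes that changed sign were not past the threshold. For Gapdh this was −0.088 with scaling on low-ratio genes and −0.011 with the compared groups alone in tubes at 200 µM, and −0.010 with the former at 800 µM. Malat1 in fixed cells at 200 µM was −0.070 with scaling on low-ratio genes. Fos in the difference at 200 µM was 0.014 with DESeq2 size factors, 0.0024 with scaling on low-ratio genes, 0.075 with DESeq2 and 0.043 with the compared groups alone. With 1 library left out, Gapdh ran from −0.25 to 0.31 and Actb from −0.18 to 0.12 in tubes at 200 µM. In tubes at 800 µM Gapdh ran from −0.13 to 0.39, Fos from −0.038 to 2.12 and Myc from −0.12 to 0.83. In fixed cells Myc ran from −0.033 to 0.47 and Malat1 from −0.14 to 0.15 at 200 µM, and Gapdh from −0.074 to 0.77, Fos from −1.10 to 1.51 and Myc from −0.55 to 0.24 at 800 µM. For the difference, Gapdh ran from −0.16 to 0.40 and Fos from −1.43 to 1.86 at 200 µM, and from −0.15 to 0.66 and −2.49 to 0.79 at 800 µM. For fixed cells against tubes Fos ran from −2.43 to 0.85 and Myc from −0.84 to 0.11. For the dose step Gapdh ran from −0.165 to 0.36 and Fos from −0.44 to 0.44 in tubes, and Gapdh from −0.26 to 0.63 in fixed cells.

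With an estimated correlation, camera called 1 list in tubes at 200 µM, 2 in tubes at 800 µM and 0 in each of the other 7 comparisons. With DESeq2 size factors it called 0 lists for the difference at 200 µM. With 1 library left out the number of lists ran from 2 to 4 and 6 to 8 in tubes at 200 and 800 µM, 0 to 1 and 0 to 3 for the difference, and 0 to 1 and 0 to 4 for the dose step in tubes and fixed cells. Without fixed 800 µM library B it called heat shock (camera BH-adjusted p = 0.00227) and S phase genes (0.012) in fixed cells at 800 µM.

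The fixed minus tube difference in loss was −3.49 at genes with at least 500 counts, where the difference in Spearman's rho was 0.0556. Against the controls of the other procedure, the loss in tubes was −30.8 at 200 µM and −37.7 at 800 µM, with rho of 0.175 and 0.202, and the difference in loss was 95.6. By design these values also hold the difference between fixed cells and tubes without 4sU, so they do not measure loss of labelled RNA alone. The ratio test called 103 and 205 genes at 200 and 800 µM with at least 500 counts, and at 800 µM 1 with at least 20 counts, 8 with the posterior mean and 1 with centred ratios. The last was Ubac2, with a logit difference of 1.72 (limma BH-adjusted p = 0.0278), named after its value was seen. The difference in the median ratio ran from −8.08 to −5.02 with 1 library left out. With each of the 8 libraries with 4sU left out in turn, the ratio test called 0 to 73 genes at 200 µM and 0 to 970 at 800 µM. Both upper values came without fixed 800 µM library B, and without library A of that group it called 68 at 200 µM.

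A replicate block, with A and B as the pairing, gave 320, 177, 68 and 238 calls for 4sU against none in tubes and then fixed cells, 3353 for fixed cells against tubes, and 0 for the differences, the dose steps and the ratio tests. The difference in loss was 4.03. The letters did not pair the samples: over 15 pairs of groups the correlation of deviations ran from −0.104 to 0.0946, and 2 of 6 groups correlated best on average with their own letter. Under the block 3 of 167 values of named genes no longer passed, and the number of called lists stayed the same in each comparison.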

Other observations

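Of the tests in this part, those on length and uracil content, on shared noise and on the loss of labelled RNA were chosen only after the result was seen, and those on the length trend and on long noncoding RNA as a class were not.

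The ratios convert to half-lives if RNA levels were steady in cells that did not grow or divide during labelling. All RNA made in the 2 h must also have been labelled and recovered like unlabelled RNA. On that reading, which the data here cannot check, list medians over the mean of the 8 libraries were 0.493 h for immediate early genes, 0.872 h for p53 targets, 2.24 h for mitosis genes, 3.03 h for S phase genes, 6.25 h for matrix genes and 11.1 h for ribosomal protein genes. The values moved with the group, by over 1.5 times for several lists. From tubes at 200 µM to fixed cells at 800 µM they went from 1.76 to 2.88 h for mitosis genes, from 2.35 to 4.15 h for S phase genes and from 3.8 to 6.32 h for endoplasmic reticulum stress. For immediate early genes and NF-kappaB targets the median ratio in fixed cells at 200 µM was 100%, which gives no half-life. Since Nr4a1 and Cdkn1a changed with 4sU, steady levels do not hold for every gene. The estimated losses of labelled RNA ran from 16.7% to 38.1% over the 8 libraries. If labelled RNA was lost to that extent, the ratios are too low and these half-lives too long. If the cells grew or divided in the 2 h, these half-lives are too short for that reason, so they bound neither side.

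Without 4sU, 62 of 78 ribosomal protein genes were higher in fixed cells than in tubes, and 3 of 6 nuclear long noncoding RNAs lower, though neither list's call held with an estimated correlation (camera BH-adjusted p = 0.268 and 0.116) and Meg3, 1 of the 3, did not pass with each library left out. The trend on transcript length as the whole cause is argued against for the ribosomal protein genes in these libraries. Their median log2 difference was 0.868 before and 0.567 after the trend was removed, above random lists matched on length (−0.0792 to 0.206). After removal it lay between 0.381 and 0.667 in the 4 pairs formed from 2 libraries of each procedure. The random lists held unrelated genes not matched on level, while the ribosomal protein genes had an estimated correlation of 0.669. The range of the random lists is therefore too narrow to bound noise common to the ribosomal protein genes. Lower recovery of long noncoding RNA as a class is a candidate explanation for the nuclear ones. The 159 lincRNA genes outside that list had a median of −0.193, against −0.0418 to 0.224 in coding genes matched on length and level. Of the 159, 7 were higher and 27 lower, beside 1796 and 1684 of all 11080 tested genes. The share called lower was thus near that of all genes, and only higher calls were fewer. The labels name no batch, so the conversion, its reaction temperature and time, and a batch of libraries cannot be told apart. No biological explanation was tested, since per the labels both groups hold the same line with no treatment.

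Genes with a high new-to-total ratio were lower in the 4sU libraries of both procedures. Transcript length or uracil content as the whole cause is argued against by the partial Spearman's rho given both. In tubes it was −0.186 and −0.198 at 200 µM and −0.229 and −0.219 at 800 µM, for A and B in turn. In fixed cells it was −0.235 and −0.344 at 200 µM and −0.307 and −0.309 at 800 µM. Each fixed library thus lay farther from 0 than each tube library of its dose, a difference that was not tested. Noise shared by a library's ratio and its count is argued against too, because with the ratio taken from the other procedure the rho was still −0.248 to −0.395. The estimated loss, which has no adjustment for length or uracil content, differed between procedures by 3.68 percentage points, within the spread between libraries. Loss of labelled RNA in handling and lower synthesis in cells given 4sU cannot be told apart on these values, since both would lower new RNA. Either may contribute, and labelling without conversion was not analysed here. Whether the trend on the ratio moved the lists that camera called with 4sU, at either dose or in either procedure, was not tested. Other causes tied to the label or to its conversion were not tested.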
